A study of Homo sapiens with 4 samples.

How the data were processed

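Gene expression was measured in HuT-102 cells, an established human line of cutaneous T cell lymphoma, on 4 Affymetrix Human Genome U133 Plus 2.0 arrays. Per the labels' protocols, cells received siRNA against IRF4 or against firefly luciferase, the control, and were kept for 60 h before total RNA was extracted, treated with DNase, amplified in a single cycle and labelled with biotin. Each group holds 2 arrays, and each array was assigned to its group from its title.

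The deposited table holds 1 linear signal intensity per probe set and array, for 54675 probe sets, and no value is on a log scale. The 2% trimmed mean of the deposited intensities was 500.08 or within 0.01 of it on every array, so the values had been scaled to a common trimmed mean before deposit. The software that summarised the probes into probe sets, its background step and any detection calls are not given in the sources used here. Arrays give no read depth, and the number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

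Signals were transformed as log2(signal + 3.51), where 3.51 is the 10th percentile of all deposited values. A log2 fold change on this scale understates the change of dim probe sets. No further step between arrays was applied because the array medians differed by 0.075 on the log2 scale, under the limit of 0.1 set beforehand. The 62 AFFX control probe sets were left out, as were probe sets whose mean was below the median of all, a signal of about 37.1, which left 27306 probe sets.

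Probe sets were named from the platform annotation supplied with the data, with symbols updated through Entrez identifiers against a RefSeq gene table of GRCh38.p14. In it 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none listed, and 41043 of those with 1 symbol were matched by identifier. A probe set with several or no symbols was left unnamed here. No genome build belongs to the deposited table, so no coordinates are given. A gene was represented by its probe set with the highest mean signal, taken among those without the cross-hybridising suffix where there were any, which gave 11754 genes.

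IRF4 siRNA was compared with luciferase siRNA in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend). Tests were two-sided and the Benjamini-Hochberg adjustment ran over all probe sets tested, with a threshold of 0.05. A rank or permutation test of 2 arrays against 2 cannot give an exact p below 0.333, so single genes were judged by limma alone. Gene lists, 35 in all with 829 distinct genes, were tested with limma's camera at a preset correlation of 0.01 between genes where at least 5 members were tested, which held for 32 lists. 4 list genes matched no current symbol. Camera with a correlation estimated for each list and limma's fry were run beside it. In each list, members were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

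The groups, tests, gene lists, alternatives and the rule for the genes to be named were fixed before the data were examined. The rule named IRF4 first, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap. It then took up to 4 passing members of each list, or the 2 members with the smallest p where fewer than 2 passed. With fewer than 24 genes past the threshold, the 24 with the smallest p were named. Genes named outside the rule are said to be so where they appear.

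The scripts were tested on simulated arrays for the comparison of IRF4 siRNA with luciferase siRNA, with 27306 probe sets, the spread of the real arrays and 200 changed genes in each of 5 simulations. A change of 0.5 on the log2 scale was recovered in 0% of genes, a change of 1 in 10%, a change of 2 in 64% and a change of 3 in 72.4%. Of the calls made, 4.19% were false. Simulations with no change gave 0 calls. In camera at an unadjusted p under 0.05, a list shifted as a whole was called in 5 of 5 simulations. An unshifted list was called in 0. The shift was larger than the median change of any list that fell in the real data. Detection of smaller shifts was therefore not tested, and 5 unshifted lists are too few for a rate of false calls. The simulated probe sets and arrays varied independently. In the real data, deviations of arrays of equal number correlated at 0.25, and the estimated correlation within a list reached 0.79. These rates of false calls therefore may not hold for the real data.

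The alternatives were quantile normalization, centring on array medians, no pseudocount or a larger pseudocount, other minimum signals, other variance models, the replicate number as a block, each array left out in turn, averaged probe sets of a gene, a fold rule, an unmoderated test and other gene set tests. An adjustment over genes alone, and lists without members of the interferon-stimulated list, were added after the data had been seen.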

Results

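IRF4 is a transcription factor of lymphocytes, and HuT-102 is a cutaneous T cell lymphoma line that grows in culture. The comparison asked which transcripts differed when IRF4 was targeted by siRNA for 60 h, against cells given siRNA to firefly luciferase, a gene these cells lack. Each group had 2 arrays. Median signals were 45.8 and 44.4 on the luciferase siRNA arrays and 46.8 and 44.2 on the IRF4 siRNA arrays. Log2 signals of the luciferase siRNA arrays correlated at r = 0.968 across probe sets and those of the IRF4 siRNA arrays at r = 0.973. Pairs of arrays from different groups lay between 0.965 and 0.975. Among these, the pairs of equal replicate number were highest, at 0.973 and 0.975. Genes are not independent replicates, and these correlations only describe the arrays. The median residual SD of a probe set was 0.24 on the log2 scale.

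The IRF4 transcript was 19.0% lower in signal after IRF4 siRNA, a difference that did not pass the test. Its brightest probe set gave 7546 ± 49.5 with luciferase siRNA and 6110 ± 801 with IRF4 siRNA (signal, SD, n = 2). Both IRF4 siRNA arrays, at 6676 and 5543, lay below both luciferase siRNA arrays, at 7581 and 7511. The log2 fold change was -0.31 ± 0.14 (SE), with a 95% interval from -0.64 to 0.02 and an adjusted p of 0.999 in limma, and it was -0.18 without IRF4 siRNA array 2. An additional IRF4 probe set had 271 ± 48.5 and 186 ± 29.6, a log2 fold change of -0.53 ± 0.27 with the same adjusted p, and the remaining one lay near the floor and was not tested. In both tested probe sets the direction was that of the labels on every array, with intervals that include 0.

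12 genes passed the test, all higher after IRF4 siRNA, and 7 of the 12 belong to the list of interferon-stimulated genes. The largest rise was that of IFNG, which encodes interferon gamma, from a signal of 27.0 ± 12.9 to 1323 ± 393. Its log2 fold change of 5.47 ± 0.38 (SE) rests in part on the pseudocount, because the control mean lies under the signal minimum of 37.1; with the control set to that minimum, IFNG was at least 31.9-fold higher, 5.00 on the log2 scale. CXCL10 and CXCL11, chemokines that attract activated T cells, rose from 2834 ± 180 to 18552 ± 658 and from 284 ± 141 to 2550 ± 136. GBP1 and GBP4, guanylate-binding GTPases induced by interferons, rose by 2.47 ± 0.17 and 2.86 ± 0.24 on the log2 scale. GBP4 is not on the interferon-stimulated list, so the 7 undercount interferon-induced genes among the 12. Among antiviral genes, IFI44L rose by 4.51 ± 0.50, XAF1 by 4.10 ± 0.27, RSAD2, which encodes viperin, by 3.74 ± 0.42, IFIT1, which binds foreign RNA, by 2.39 ± 0.19, and SAMD9L by 1.76 ± 0.17. The transcription factor IRF1 rose from 2036 ± 94.0 to 5708 ± 733, a log2 fold change of 1.48 ± 0.16. PARP14, an ADP-ribosyltransferase, rose by 1.55 ± 0.17, while its other tested probe set had a value of -0.53 ± 0.51.

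Adjusted p for these genes ran from 0.00191 for CXCL10 to 0.0435 for IFI44L and RSAD2, with IFNG, XAF1 and GBP1 at 0.00783. By probe set, 21 passed and all were higher, 2 of them without a symbol in the annotation used. With the replicate number as a block, 353 genes passed, 283 higher and 70 lower, though the labels do not say what the number marks. With all 4 arrays and no block, 0 genes passed with a lower signal in limma, against 190 at an unadjusted p under 0.05, where 416 genes were higher. Leaving out luciferase siRNA array 1 gave 71 passing genes, luciferase siRNA array 2 gave 26, IRF4 siRNA array 1 gave 22 and IRF4 siRNA array 2 gave 47, with the same 12 among them each time; 1, 1, 3 and 1 of the passing genes, in that order, were lower. The count was 24 with the signal minimum at the 25th percentile, 5 at the 75th, and 0 without the intensity trend, where 558 genes had an unadjusted p under 0.05. Between the groups, the 3'-to-5' log2 difference of the ACTB control probe sets also separated, at 0.232 and 0.216 with luciferase siRNA and 0.160 and 0.155 with IRF4 siRNA.

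**Figure D1:**
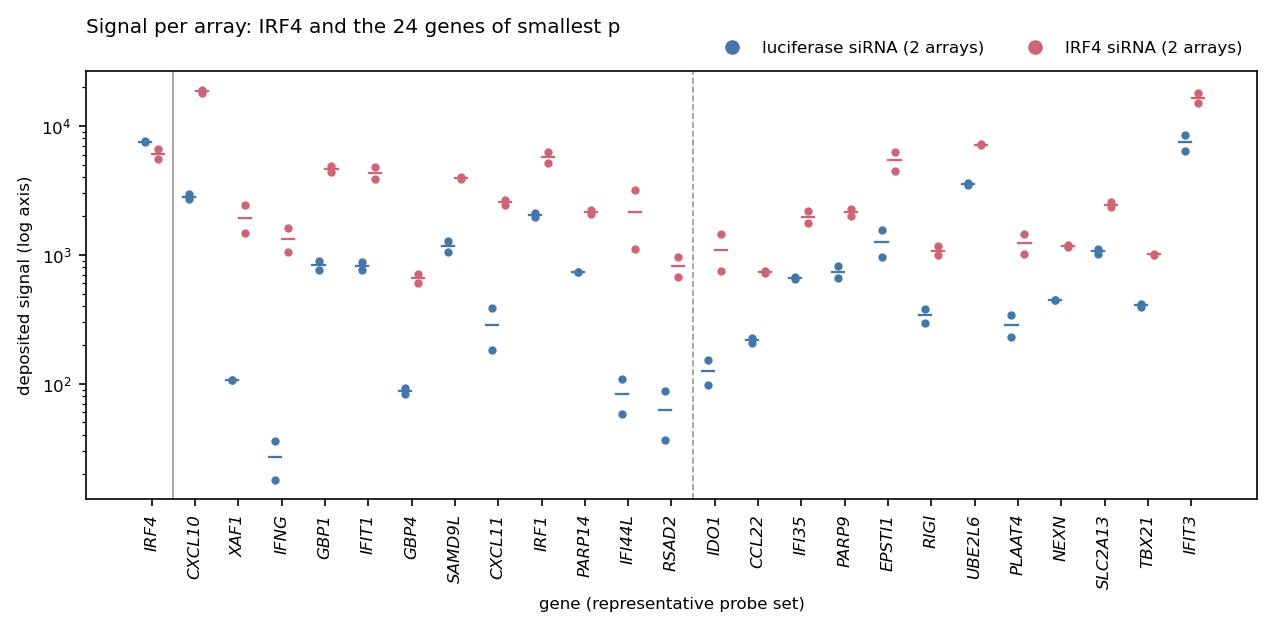
Signal of IRF4 and of the 24 genes with the smallest p on each of the 4 arrays, on a log axis, with 1 point per array, blue for luciferase siRNA and red for IRF4 siRNA, and short bars for the group means; the solid line sets IRF4 apart, and the dashed line separates the 12 genes past adjusted p 0.05 from the 12 that did not pass. IFNG went from 27.0 to 1323 in mean signal, whereas IRF4 went from 7546 to 6110.

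The next 12 genes by p had higher signals after IRF4 siRNA but did not pass. IDO1, which breaks down tryptophan, had a mean signal of 125 with luciferase siRNA and 1098 with IRF4 siRNA (log2 fold change 3.05 ± 0.36, adjusted p = 0.0521). CCL22, a chemokine for CCR4-bearing T cells, had 218 and 735 (1.74 ± 0.21, adjusted p = 0.0521). Log2 fold changes were 1.57 for IFI35, 1.53 for PARP9, 2.13 for EPSTI1, 1.67 for the RNA sensor RIGI, 1.01 for the ISG15-conjugating enzyme UBE2L6, 2.10 for PLAAT4 and 1.16 for IFIT3. The remaining 3 were NEXN at 1.39, the sugar transporter gene SLC2A13 at 1.21 and TBX21, the T-bet transcription factor of interferon gamma-producing T cells, at 1.31. In all, 13 of the 24 genes with the smallest p belong to the interferon-stimulated list.

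Interferon-stimulated genes rose as a group: all 48 tested members had a positive log2 fold change, with a median of 1.18. Camera gave an adjusted p of 2.68e-65 with the preset correlation, and the adjusted p was 0.244 with an estimated correlation. 7 members passed over all probe sets, and 41 passed adjusted over the list alone. The list's median log2 signal was 9.87 and 9.59 on the luciferase siRNA arrays and 11.20 and 10.81 on the IRF4 siRNA arrays. With 1 array left out in turn its median ran from 0.97 to 1.49. None of the 21 lists past the threshold with the preset correlation passed with an estimated correlation or with fry, where the smallest adjusted p was 0.244 and 0.0521. With these, 6 and 8 lists had an unadjusted p under 0.05. Both methods rest on 2 residual degrees of freedom. The estimated correlation was 0.53 for the interferon-stimulated list but -0.0089 for the cytokine list, under the preset 0.01. Correlation between genes therefore does not account for the loss of the cytokine list.

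Other immune lists rose as well by camera with the preset correlation. The IRF family list left out IRF4, the target. Of its 7 tested members 6 were higher, with a median of 0.45 (adjusted p = 4.08e-06, or 0.244 with an estimated correlation). That median was 0.26 without IRF4 siRNA array 1. Without IRF7 and IRF9, its 2 members on the interferon-stimulated list, it was 0.17 (adjusted p = 0.00577, or 0.337 with an estimated correlation). IRF1 passed, and IRF9 and IRF7, which act downstream of interferon, had log2 fold changes of 1.24 ± 0.20 and 1.62 ± 0.31; 3 members passed adjusted over the list alone. The list of innate RNA sensing and interferon induction had 13 of 17 members higher and a median of 0.36 (adjusted p = 2.70e-05, and adjusted p = 0.244 with an estimated correlation). Its median was 0.21 without either luciferase siRNA array 1 or IRF4 siRNA array 1. Without its 4 members on the interferon-stimulated list it was 0.15 (adjusted p = 0.00908, or 0.337 with an estimated correlation). Its passing member was IFNG, and IFIH1, which senses long double-stranded RNA, had 0.91 ± 0.23. Of 18 MHC class I presentation genes 16 were higher, with a median of 0.40 (adjusted p = 7.65e-10, or 0.319 with an estimated correlation). The median was 0.36 without TAP1, the 1 member also on the interferon-stimulated list, and 0.24 without IRF4 siRNA array 1. None passed over all probe sets and 8 passed adjusted over the list alone, among them the peptide transporter TAP1 at 0.70 ± 0.12 and the immunoproteasome subunit PSMB9 at 1.22 ± 0.23.

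NF-kB targets and cytokine genes showed the same sign, in lists that share CXCL10 and CCL22 and are not independent. Of 28 NF-kB targets 22 were higher, with a median of 0.37 (adjusted p = 2.13e-11, and adjusted p = 0.244 with an estimated correlation). CXCL10 passed, and 9 members passed adjusted over the list alone, including the adhesion molecule ICAM1 at 0.62 ± 0.12 and CCL22. Of 30 cytokines, chemokines and their receptors 24 were higher, with a median of 0.45 and the same adjusted p values; CXCL10 and CXCL11 passed, and 8 members passed adjusted over the list alone. CCR4, a chemokine receptor of skin-homing T cells, had a lower signal, 91.7 against 40.0, with a log2 fold change of -1.12 ± 0.44 that did not pass. Of 24 apoptosis regulators 18 were higher, with a median of 0.17 (adjusted p = 2.70e-05, and adjusted p = 0.244 with an estimated correlation). The median was 0.10 without luciferase siRNA array 2. None passed by its representative probe set and 5 passed adjusted over the list alone, among them TNFSF10, which encodes the death ligand TRAIL, at 1.69 ± 0.25 and CFLAR, an inhibitor of caspase-8 activation, at 0.83 ± 0.16. A different TNFSF10 probe set did pass, at 1.54 ± 0.16 (adjusted p = 0.0390). The 11 other tested CFLAR probe sets were also higher. The brightest of them, with the cross-hybridising suffix, had smaller values, 0.28 ± 0.18 and 0.35 ± 0.18. The list of IRF4 partners and plasma or B lineage factors had 15 of 17 members higher and a median of 0.24 (adjusted p = 1.83e-04, and adjusted p = 0.244 with an estimated correlation). Its members with the smallest p were JUN at 0.52 ± 0.16 and STAT3 at 0.45 ± 0.14, with none past the threshold. These 7 lists stayed past the threshold with any 1 array left out.

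**Figure D2:**
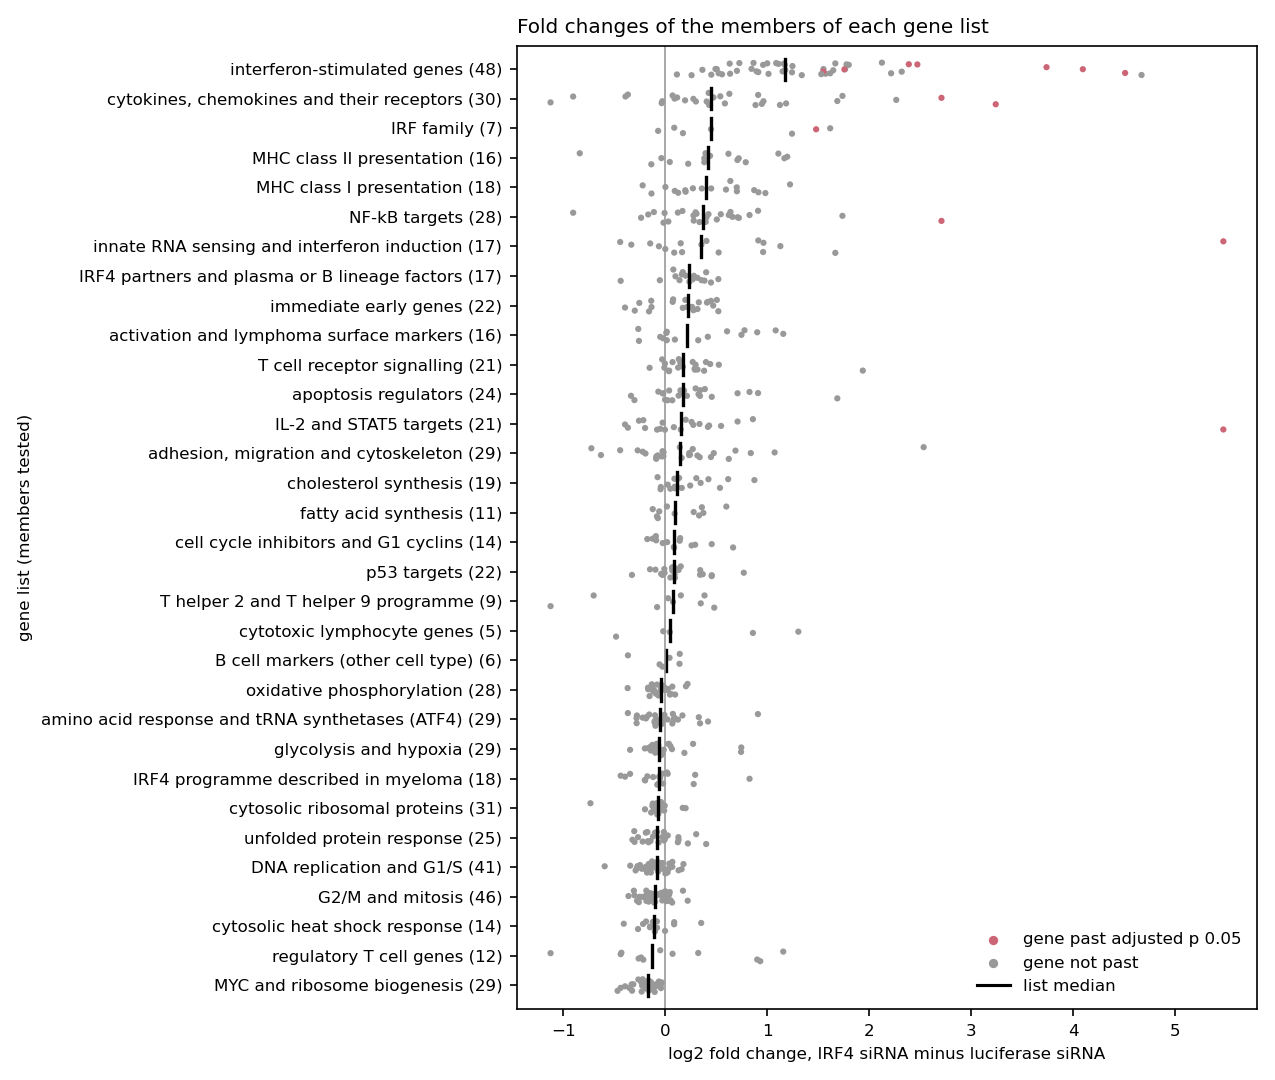
Median log2 fold change (IRF4 siRNA minus luciferase siRNA, horizontal axis) of each tested gene list (vertical axis), as black bars, over points for its tested members, red for genes past adjusted p 0.05 and grey for the others; the number of members tested stands beside each list's name. The interferon-stimulated list has the highest median, 1.18, and the lowest is -0.17 for MYC and ribosome biogenesis.

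8 further lists with higher medians passed camera with the preset correlation but not with some array left out. MHC class II presentation had 13 of 16 members higher, a median of 0.42 and an adjusted p of 2.74e-04, against an adjusted p of 0.477 with an estimated correlation. HLA-DQA1 had 1.20 ± 0.50 and CTSS, which encodes cathepsin S, 0.72 ± 0.20, and none passed. With 1 array left out the list's median ran from 0.15 to 0.73, with an adjusted p of 0.135 without luciferase siRNA array 2 and 0.0670 without IRF4 siRNA array 1. T cell receptor signalling had 17 of 21 members higher and a median of 0.17 (adjusted p = 0.00538, and adjusted p = 0.558 with an estimated correlation). PRKCQ, the T cell isoform of protein kinase C, had mean signals of 27.0 and 111, a log2 fold change of 1.94 ± 0.48 that is at least 1.49 with the control set to the signal minimum, and the kinase FYN had 0.40 ± 0.21. The list's median ran from 0.04 to 0.40 with 1 array left out. Its adjusted p was 0.271 without luciferase siRNA array 2, 0.671 without IRF4 siRNA array 1 and 0.0537 with each gene's probe sets averaged. Activation and lymphoma surface markers had 12 of 16 members higher and a median of 0.21 (adjusted p = 0.00310, and adjusted p = 0.486 with an estimated correlation). The inhibitory ligand CD274 had 1.08 ± 0.17 and the costimulatory ligand CD86 0.61 ± 0.15, and 3 members passed adjusted over the list alone. That list's median ran from 0.08 to 0.46 with 1 array left out, with an adjusted p of 0.378 without luciferase siRNA array 2 and 0.127 without IRF4 siRNA array 1.

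IL-2 and STAT5 targets had 12 of 21 members higher and a median of 0.15 (adjusted p = 0.00913, and adjusted p = 0.319 with an estimated correlation), with IFNG past the threshold and BCL2L1, an inhibitor of apoptosis, at 0.71 ± 0.16. The median ran from 0.04 to 0.21 with 1 array left out, and the adjusted p was 0.0534 without IRF4 siRNA array 2 and 0.0821 with the signal minimum at the 75th percentile. Immediate early genes had 16 of 22 members higher and a median of 0.23 (adjusted p = 0.00754, and adjusted p = 0.319 with an estimated correlation), with IER3 at 0.51 ± 0.14. Their median was 0.01 without luciferase siRNA array 2 (adjusted p = 0.223), and the adjusted p was 0.0534 without IRF4 siRNA array 2. Adhesion, migration and cytoskeleton genes had 15 of 29 members higher and a median of 0.14 (adjusted p = 0.0220, and adjusted p = 0.531 with an estimated correlation), with VCAM1 at 1.07 ± 0.18. Their median ran from 0.03 to 0.28 with 1 array left out. The adjusted p was 0.390 without luciferase siRNA array 2, 0.179 without IRF4 siRNA array 1 and 0.102 with no signal minimum, where the median was -0.02. Cholesterol synthesis had 16 of 19 members higher and a median of 0.12 (adjusted p = 0.00761, and adjusted p = 0.558 with an estimated correlation), with MVD at 0.62 ± 0.30 and TM7SF2 at 0.42 ± 0.19. Its median was -0.01 without luciferase siRNA array 2 (adjusted p = 0.916), -0.03 without IRF4 siRNA array 1 (adjusted p = 0.786) and up to 0.36 without another. Among p53 targets 15 of 22 were higher, with a median of 0.08 (adjusted p = 0.0161, and adjusted p = 0.546 with an estimated correlation). PMAIP1, a pro-apoptotic BH3 protein also called NOXA, had 0.46 ± 0.11 and CDKN1A 0.46 ± 0.17. The other tested PMAIP1 probe set had a larger value, 0.92 ± 0.11, that did not pass in limma (adjusted p = 0.0521). The list's median ran from 7.50e-04 without IRF4 siRNA array 2 to 0.23 without IRF4 siRNA array 1.

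5 lists fell by small amounts in camera with the preset correlation. All 29 tested genes of the MYC and ribosome biogenesis list had a negative value, with a median of -0.17 (adjusted p = 1.64e-05, and adjusted p = 0.531 with an estimated correlation). MYC had a mean signal of 9575 with luciferase siRNA and 7286 with IRF4 siRNA, a log2 fold change of -0.39 ± 0.12, and fibrillarin, encoded by FBL, had -0.33 ± 0.11; neither passed. The list's median was -0.01 without luciferase siRNA array 2 (adjusted p = 0.673), -0.04 without IRF4 siRNA array 1 (adjusted p = 0.360), -0.38 without luciferase siRNA array 1 and -0.31 without IRF4 siRNA array 2. G2/M and mitosis genes were lower in 33 of 46 cases, with a median of -0.10 (adjusted p = 0.00428, and adjusted p = 0.382 with an estimated correlation), and SPC25 had -0.36 ± 0.16 and BIRC5 -0.30 ± 0.14. Without luciferase siRNA array 2 their adjusted p was 0.184. DNA replication and G1/S genes were lower in 30 of 41 cases, with a median of -0.08 (adjusted p = 0.00538, and adjusted p = 0.486 with an estimated correlation), and POLE2 had -0.59 ± 0.23. Their median ran from -0.19 to -0.05 with 1 array left out, and the adjusted p was 0.284 without luciferase siRNA array 2 and 0.365 without IRF4 siRNA array 1.

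Cytosolic ribosomal protein genes were lower in 29 of 31 cases, with a median of -0.08 (adjusted p = 0.00460, and adjusted p = 0.662 with an estimated correlation). Their median ran from -0.16 to 0.03 with 1 array left out, and the adjusted p was 0.642 without luciferase siRNA array 1, 0.105 without IRF4 siRNA array 2 and 0.707 after quantile normalization. The cytosolic heat shock response was lower in 11 of 14 genes, with a median of -0.11 (adjusted p = 0.0497, and adjusted p = 0.403 with an estimated correlation). The mitochondrial chaperonin subunit HSPE1 had -0.41 ± 0.10 and HSPH1 -0.27 ± 0.12. Its median ran from -0.15 to -0.02 with 1 array left out. The adjusted p was 0.0539 without luciferase siRNA array 1, 0.352 without luciferase siRNA array 2, 0.412 without IRF4 siRNA array 1 and 0.162 after quantile normalization, and between 0.0554 and 0.289 with other signal minimums.

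The IRF4 programme described in myeloma did not pass, with 13 of 18 members lower and a median of -0.06 (adjusted p = 0.381). Regulatory T cell genes had a median of -0.13 and a mean of 0.05 (adjusted p = 0.712), with the activation receptor TNFRSF9 at 1.16 ± 0.30 and the ectonucleotidase ENTPD1 at 0.93 ± 0.27. The T helper 2 and T helper 9 programme had a median of 0.08 and a mean of -0.05 (adjusted p = 0.556), with IL4R at 0.35 ± 0.16. Cytotoxic lymphocyte genes, 5 tested, had a median of 0.04 (adjusted p = 0.0731); TBX21 passed adjusted over the list alone, and perforin, encoded by PRF1, had 0.86 ± 0.44. Their adjusted p was 0.0194 without IRF4 siRNA array 2. Cell cycle inhibitors and G1 cyclins had a median of 0.09 (adjusted p = 0.115), with CDKN2D at 0.67 ± 0.24.

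The amino acid response list had a median of -0.05 (adjusted p = 0.711), yet its adjusted p was 0.0436 without luciferase siRNA array 1, 3.00e-04 without IRF4 siRNA array 1, where the median was 0.20, and 1.12e-04 without IRF4 siRNA array 2. WARS1, the interferon-inducible tryptophanyl-tRNA synthetase, had 0.91 ± 0.14, and PHGDH had -0.37 ± 0.18. Glycolysis and hypoxia genes had a median of -0.06 and a mean of 0.0017 (adjusted p = 0.248). Their median was 0.15 without luciferase siRNA array 1 (adjusted p = 0.00312), -0.29 without luciferase siRNA array 2 (5.30e-08) and -0.18 without IRF4 siRNA array 1 (0.00164). The unfolded protein response had a median of -0.08 (adjusted p = 0.136, and 0.0194 without IRF4 siRNA array 2), with HSP90B1 at -0.30 ± 0.12. Fatty acid synthesis had a median of 0.09 (adjusted p = 0.164, with 0.0108 without luciferase siRNA array 1 and 0.0194 without IRF4 siRNA array 2), with SCD at 0.28 ± 0.14. Oxidative phosphorylation had a median of -0.04 (adjusted p = 0.164, and 0.00941 without luciferase siRNA array 2), with SDHC at -0.37 ± 0.17.

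Markers of other cell types did not move with the treatment past the threshold. B cell markers, 6 tested, had a median of 0.01 that changed sign with quantile normalization and with centring (adjusted p = 0.711), although PAX5 and BLK, genes of the B lineage, were bright in both groups, with mean signals of 1492 and 1645 for PAX5 and 609 and 671 for BLK. Of the monocyte and macrophage markers 1 of 12 was bright enough to test, of the fibroblast and epithelial markers 4 of 13 and of the erythroid and platelet markers 1 of 7, so these lists were not tested as groups, and 0 members of any of them passed in limma. Their median signals were 22.2, 24.2 and 21.3 with luciferase siRNA and 19.6, 20.2 and 31.9 with IRF4 siRNA. The 3'-to-5' log2 difference of the GAPDH control probe sets was -0.116 and -0.111 with luciferase siRNA and -0.113 and -0.122 with IRF4 siRNA. The control probe set for 18S ribosomal RNA gave 9288 and 2278 with luciferase siRNA and 4984 and 3493 with IRF4 siRNA.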

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

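The tests in this part were chosen only after the results had been seen, except quantile normalization, the replicate number as a block, and the comparisons of replicate arrays for the lists of MYC and ribosome biogenesis, G2/M, and DNA replication. The transcript of IFNB1, which encodes interferon beta, stood out in data outside the tests, because its probe set was below the signal minimum. Its signal was 6.84 and 2.66 on the luciferase siRNA arrays and 69.3 and 82.5 on the IRF4 siRNA arrays, a log2 fold change of 3.31 with no test. The control signals are near the floor, so this value depends on background and pseudocount; with the control set to the signal minimum it is at least 0.96.

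The interferon-stimulated list rose by a median of 1.18. A difference in array brightness or scaling is argued against by a median of 1.21 after quantile normalization. A day or batch shared by arrays of equal number largely cancels between the groups, because both groups hold both numbers. The number-matched differences were 1.25 and 1.16, both above the largest difference between replicate arrays, 0.46. They cannot test a batch that divides the groups, since each of them holds the same division. A response to the IRF4 duplexes themselves cannot be told apart from a response to loss of IRF4, because the design holds 1 IRF4 siRNA group and the IRF4 transcript had a log2 fold change of only -0.31. Both remain candidate explanations, and the loss of IRF4, the difference the design names, is untested.

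The counts of passing genes and probe sets were set against the other splits of the 4 arrays into pairs. In 2 of the 3 splits as many genes passed, and likewise for probe sets in 2 of the 3, with 12 genes and 21 probe sets for the real split and at most 12 and 22 for the others. The 3 splits are too few for a share under 0.05. The split that matched was that of the arrays numbered 1 against those numbered 2. In this split the treatment difference counts as residual spread. Genes with a large treatment difference could hardly pass in it, so a lack of overlap with the real split decides nothing. None of the 12 genes of the split by number was among the 12 of the real split. In the split by number, 0 members of the interferon-stimulated list passed in limma. That list nevertheless had a median of 0.41 in it (adjusted p = 0.0189 in camera with the preset correlation and 0.981 with an estimated one), and 14 lists passed in it with the preset correlation, against 21 in the real split, and 0 in either with an estimated one. With the replicate number as a block, 353 genes passed in the real comparison, and 42 of the 48 tested interferon-stimulated genes were among them.

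The IRF4 signal was only 19.0% lower. The highest signal on every array was at least 7.29 times the IRF4 signal of the controls. Signal levels of different probe sets are not directly comparable, so this cannot decide whether the brightest IRF4 probe set was near saturation. The dimmer tested IRF4 probe set was 31.3% lower, and saturation stays open. Weak silencing of the transcript, or recovery by 60 h, may lie behind the small difference, and neither was tested, since IRF4 protein and earlier times were not analysed here.

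The lists of MYC and ribosome biogenesis, G2/M and mitosis, and DNA replication and G1/S had medians of -0.17, -0.10 and -0.08. A shift that depends on brightness alone is argued against for the first, at percentile 0 of 10000 random lists matched on mean signal, and for G2/M, at percentile 0.43. It stays open for DNA replication, at percentile 3.88, as it does for ribosomal proteins and the heat shock response, at 19.4 and 4.13. The random lists lack the correlation within a list, estimated at 0.53 for the first and 0.03 for G2/M. The percentiles therefore cannot exclude brightness combined with noise shared by a list. A difference between arrays unrelated to the treatment stays open for the first list, whose median differed by 0.345 between replicate arrays although its number-matched differences were -0.18 and -0.20, and for DNA replication, at 0.0981. For G2/M the larger such difference was 0.0512, with an SE of 0.0317 computed afterwards, too close to the bound of 0.0519 set beforehand to decide. An effect of the IRF4 siRNA, the difference the design names, also stays open and untested.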

How the results depend on the processing

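All 12 passing genes kept their direction in every setting that tested them. The IRF4 log2 fold change ran from -0.44 to -0.18 and never passed. The counts were more fragile. With the signal minimum at the 25th percentile, 40 probe sets and 24 genes passed; at the 75th, 9 and 5 did, where 9 of the 12 genes were tested. Without the intensity trend in eBayes, 0 probe sets and 0 genes passed, against 1394 and 558 at an unadjusted p under 0.05, and an unmoderated test per probe set passed 0 genes, against 646. A fold rule, with every IRF4 siRNA array at least 2-fold beyond every control array, took 86 genes, 68 higher and 18 lower, but it also took 86 between the arrays numbered 1 and 2, 59 higher and 27 lower. Camera with estimated correlations and fry each passed 0 lists, against 6 and 8 at an unadjusted p. The last 2 methods rest on 2 residual degrees of freedom. Beyond the smaller number of genes tested at the 75th percentile, the cause was not tested.

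With the replicate number as a block, 599 probe sets and 353 genes passed, 283 higher and 70 lower, the 12 genes among them. Deviations from the group means correlated at 0.25 between arrays of equal number, and the labels do not say that a number marks a day or culture. IRF4 did not pass (adjusted p = 0.129), and the same 21 lists did.

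Leaving out 1 array at a time, where the lone array is assumed to vary like the other group, gave 42 to 118 probe sets, 22 to 71 genes and 13 to 21 lists. Camera's direction turned for p53 targets, with medians of 7.50e-04 to 0.233, and medians changed sign for the amino acid response, -0.24 to 0.20, glycolysis and hypoxia, -0.29 to 0.15, cytosolic ribosomal proteins, -0.164 to 0.0276, and cholesterol synthesis, -0.026 to 0.361. Further lists that did not pass changed sign too: fatty acid synthesis, -0.0057 to 0.401, oxidative phosphorylation, -0.139 to 0.0404, regulatory T cell genes, -0.207 to 0.146, the unfolded protein response, -0.157 to 0.0193, cytotoxic lymphocyte genes, -0.0023 to 0.673, and B cell markers, -0.0025 to 0.119. The cause was not tested. Averaging each gene's probe sets, which differ in sign, turned ELOVL6 to -0.0335 and ENO1 to 0.0176. Quantile normalization, centring, other pseudocounts, no signal minimum, robust eBayes and, added after the data had been seen, adjustment over genes alone left 8 to 17 genes. Taking members of the interferon-stimulated list out of the other lists, also added then, left 21 lists. Only 3 other lists held such members, so the count tests little. Interferon-inducible genes that are not on that list, such as WARS1, stayed in. Probe sets with a mean signal under 37.1 lie near background and were not tested, so dim transcripts such as IFNB1 have no p.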

Other observations

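The values in this part were looked at only after the results had been seen. Between the arrays numbered 1 and those numbered 2, 12 genes passed in limma, 9 of them higher on the arrays numbered 1 in both groups. Among them were HILPDA, PDK1, ANKRD37 and SLC2A3, genes known to be induced by hypoxia, with log2 differences of 1.79 ± 0.13, 1.97 ± 0.17, 1.45 ± 0.12 and 1.86 ± 0.19 (SE). The signal of PDK1, a kinase that restrains pyruvate dehydrogenase, was 3327 and 2497 on the arrays numbered 1 and 731 and 738 on those numbered 2. SLC7A5, an amino acid transporter gene, was lower on the arrays numbered 1, with a log2 difference of -1.34 ± 0.13, as were the histone genes H2BC12 at -1.15 and H2AC6 at -1.97. The glycolysis and hypoxia list had a median of 0.30 (adjusted p = 1.00e-10 in camera with the preset correlation), the amino acid response list -0.31 (1.11e-08), MYC and ribosome biogenesis -0.32 (4.85e-09) and cholesterol synthesis 0.39 (2.73e-05). With an estimated correlation the adjusted p of each of these 4 lists was 0.870.

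Of the interferon genes named in the annotation, IFNG passed, and IFNL1, an interferon lambda gene, had a mean signal of 27.3 ± 19.7 with luciferase siRNA and 95.1 ± 0.547 with IRF4 siRNA (SD, n = 2), the first of them under the signal minimum. Most interferon alpha genes were dim in both groups, such as IFNA1 with mean signals of 12.7 and 12.9, and IFNA17, the brightest, had 112 with luciferase siRNA and 68.0 with IRF4 siRNA. With all 4 arrays and no block no gene with a lower signal passed, while 70 did with the replicate number as a block. Without the block, the lower gene with the smallest p was LINC01588, at a log2 fold change of -1.27 ± 0.19 (adjusted p = 0.125 in limma). It was followed by LINC01943 at -1.39 ± 0.24, TSPAN13 at -0.75 ± 0.14, TPRG1 at -0.84 ± 0.16 and HMGA1 at -0.68 ± 0.14.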
